A study of Solanum tuberosum with 6 samples.

How the data were processed

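The series measured polyadenylated RNA of wild-type potato (Solanum tuberosum) cells by RNA sequencing in 6 libraries, 3 from RNA of purified mitochondria and 3 from total RNA. Per the labels' protocols, both kinds of RNA were extracted with Tri Reagent and treated with DNase, and the extraction of total RNA was modified to remove starch. Cytosolic mRNAs were then purified on oligo-dT beads, which leaves behind most mRNAs made inside mitochondria, because stable ones carry no poly(A) tail. Libraries followed standard Illumina protocols, and whether they kept strand is not given in the sources used here.

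Per the submitters' processing notes, the authors used CASAVA 1.8.2, TopHat2 2.0.8b, Bowtie2 2.1.0, HTSeq 0.5.4p3 and DESeq2. The genome build and the gene annotation are not given in the sources used here. Per the file headers and values, each library's deposited table holds whole-number read counts per gene for the same 15181 gene IDs, which begin with PGSC0003DMG. These counts are not normalised. The lowest count in any total RNA library was 50, while the mitochondria-associated libraries reached 0, so the tables list only genes with at least 50 counts in each of the 3 total RNA libraries. A gene below that level in total RNA is therefore not analysed here, however abundant it is at mitochondria. The deposited tables hold no rows for unassigned reads. The authors' deposited comparison table gives, for the same 15181 genes, the mean normalised count (a signal scaled by size factors), the log2 fold change, its standard error, a Wald statistic (a score), the p-value and the adjusted p-value. Its mean normalised counts differed from those recomputed from the count tables by at most 4.9e-08%, and its fold changes are mitochondria-associated over total RNA.

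The IDs in the files are not paired with gene names, and 0 of them matched the 32873 genes of the potato RefSeq table for assembly SolTub_3.0. The 22 lists of gene descriptions fixed before the data were examined (mitochondrial, plastid, endoplasmic reticulum, cytosolic and nuclear proteins) could therefore not be applied. For the same reason the planned comparisons of upstream AUGs and of transcript length and GC content were not analysed here. The rule for named genes in this case was at most 2 IDs that rose and 2 that fell. They are the 2 largest and the 2 smallest log2 fold changes among genes with an adjusted p below 0.05, a mean CPM (the count scaled to the size of its library) of at least 10, and all 3 libraries of one group on the same side of the other.

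Groups were taken from the sample titles. Counts were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1), with trimmed mean of M-values (TMM) scaling, edgeR's filterByExpr, the quasi-likelihood F test and Benjamini-Hochberg adjustment over all genes, at an adjusted p of 0.05. The filter removed 0 genes. Standard errors of log2 fold changes were obtained as the fold change divided by the square root of F. CPM values are TMM-scaled, and fold changes are relative to the other mRNAs of a library, not amounts per cell or per mitochondrion. Where all 3 mitochondria-associated libraries had 0 counts, a fold was computed against a floor of 3 counts over the pooled libraries and is a lower bound, covering counting error only. Abundance deciles were formed from the mean CPM over all 6 libraries. Labels call the libraries triplicates without naming separate cultures or preparations, so p-values measure only the spread between these libraries, which may be technical. Counts of replicates were compared with a chi-square statistic per degree of freedom, which ranged from 39.8 to 537, so no pair of libraries was a repeat of another within sampling noise.

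Both groups carry replicate numbers 1 to 3. Deviations from the group means correlated at 0.40 between libraries numbered 1, 0.38 between those numbered 2 and -0.05 between those numbered 3. Deviations within a group cancel out, so these values are not independent of each other and do not exclude pairing. The numbers were not taken to pair the samples and no block was used in the main test.

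The test was tested on simulated data with the real means and library sizes of this comparison and 15181 genes, 200 of them changed. The simulated spread followed edgeR's trend of spread over abundance. Spread particular to single genes, and deviations shared between libraries, were left out. At the same threshold it called 14 of 100 genes changed 2-fold and 76 of 100 changed 4-fold, and 4 unchanged genes. The alternatives fixed in advance were DESeq2 size factors, upper quartile scaling, library size alone, no low-count filter, a minimum of 50 counts in 3 samples, DESeq2 1.42.0 (32 adjusted p-values were not given), limma-voom, a replicate block and leaving out each library. A minimum mean of 10 CPM, thinning of total RNA to 23544101 counts per library, leaving out replicate 1 of both groups, and TMM factors shifted to centre the lower 5 abundance deciles were added after the data were seen.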

Results

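Polyadenylated RNA was sequenced from purified mitochondria of potato and from total potato RNA, with 3 libraries of each kind. Selection for poly(A) tails keeps cytosolic mRNAs, which come from nuclear genes, and removes most mRNAs made inside the organelle. The comparison of both kinds of RNA addresses which cytosolic mRNAs are found at mitochondria. The mitochondria-associated libraries held 23056535, 12799068 and 34776699 counts (replicates 1 to 3), and the total RNA libraries held 54599781, 85355383 and 82842146 counts. Each table listed 15181 genes, all with at least 50 counts in every total RNA library. Pearson's r of log2 CPM across genes was 0.922 to 0.979 within mitochondria-associated RNA, 0.938 to 0.968 within total RNA and 0.784 to 0.914 between them. Spearman correlations did not separate them as fully, at 0.927 to 0.984, 0.938 to 0.968 and 0.825 to 0.940. The first principal component held 68.3% of the variance and separated both kinds of RNA. The second held 18.9% and placed the libraries numbered 1 of both kinds apart from the other 4.

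The mRNA population at mitochondria differed from that of total RNA in 2854 of 15181 genes (18.8%), and more of the listed genes were lower than higher, though this order turned when the scaling was centred on rarer genes. Of the 2854 genes, 860 were higher in mitochondria-associated RNA, with a median log2 fold change of 1.04 (quartiles 0.86 and 1.39), that is 2.06-fold. The other 1994 were lower, with a median log2 fold change of -2.03 (quartiles -3.59 and -1.34), that is 4.08-fold lower. Past 2-fold, 473 genes were higher and 1826 lower. Among called genes with a mean of at least 20 CPM and log2 changes of 1 to 4 in size, which the minimum of 50 counts in total RNA leaves in place, 253 were higher and 421 lower, a ratio of 1.66 (1.33 without mitochondria-associated replicate 3). Past 4-fold, 75 were higher and 1010 lower, and past 8-fold 5 were higher and 618 lower. The minimum leaves out genes that are rare in total RNA and much higher at mitochondria, so it adds to this difference. At a mean of at least 20 CPM and log2 changes of 2 to 4 in size, 23 called genes were higher and 100 lower. Genes without any mitochondria-associated count had lower bounds of at least 17.9-fold, beyond 8-fold and the outer quartile. Setting them to these bounds therefore could not change the counts past 4-fold and 8-fold, the median or the quartiles, and tested nothing. Calls rest on edgeR's quasi-likelihood test with a Benjamini-Hochberg adjusted p below 0.05 (n = 3 per group). All 3 mitochondria-associated libraries lay above all 3 total RNA libraries in 2986 genes (19.7%) and below them in 3476 (22.9%), where chance gives 5% each for a single gene. Genes share the deviations of whole libraries, so shares across genes can lie far from 5% by chance and are not a test. With library size as the sole scaling, which moved the median log2 fold change of all genes from 0.01 to -0.15, 427 genes were higher and 2381 lower. With TMM factors shifted by 0.23 on the log2 scale, so that the median log2 fold change of the lower 5 abundance deciles was 0, 2213 genes were higher and 1634 lower. Past 2-fold, 1188 of them were higher and 1489 lower past 2-fold, and 122 and 885 past 4-fold. The counts also depended on single libraries: there were 133 higher and 1031 lower genes without mitochondria-associated replicate 2, 134 and 1024 without total RNA replicate 2, 312 and 1416 without total RNA replicate 1, and 529 and 1680 without total RNA replicate 3.

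**Figure D1:**
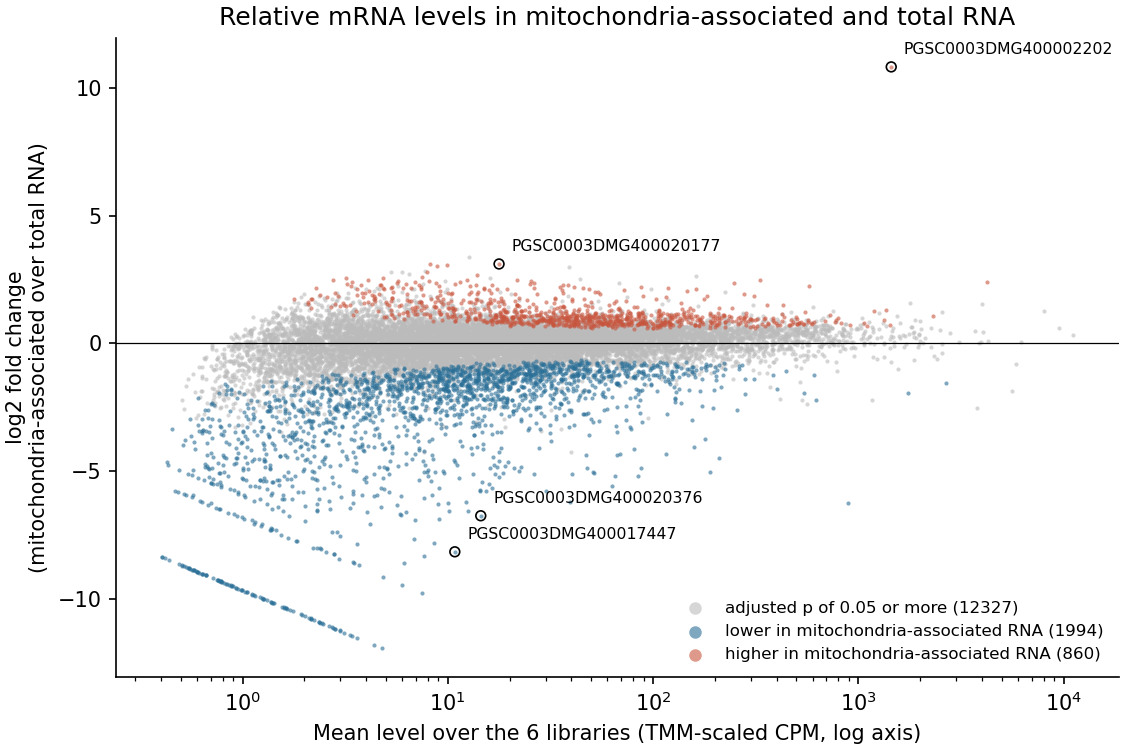
Each point is 1 of the 15181 genes, with its mean TMM-scaled CPM over the 6 libraries on a log axis and its fitted log2 fold change (mitochondria-associated over total RNA); red and blue mark the 860 higher and 1994 lower genes and circles the 4 named genes. Lower genes spread much further from 0 than higher genes, and the straight bands at the bottom left are genes with 0 or very few counts in mitochondria-associated RNA, whose fitted fold changes are not sizes to be read off.

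The enriched and depleted gene groups made up small parts of the sequenced RNA. The 860 enriched genes took 11.3% ± 1.43 of all counts in mitochondria-associated RNA and 5.95% ± 0.423 in total RNA (SD, n = 3 each). The 1994 depleted genes took 2.45% ± 0.169 of the counts in mitochondria-associated RNA and 8.34% ± 1.60 in total RNA (SD, n = 3 each). Genes called and more than 8-fold lower held 1.16% ± 0.351 of total RNA counts and 0.0515% ± 0.0101 of mitochondria-associated counts (SD, n = 3 each). These groups were chosen on the same libraries, so the shares describe them and are not a further test.

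Among the listed genes, a single gene stood far above all others in log2 fold change. Genes below the minimum of counts in total RNA are not listed, so whether any of them rose as far was not tested. PGSC0003DMG400002202 had 47371, 66146 and 37783 counts in the mitochondria-associated libraries and 65, 150 and 173 in the total RNA libraries. Its level was 2892 ± 2166 CPM in mitochondria-associated RNA and 1.59 ± 0.450 CPM in total RNA (SD, n = 3 each), a log2 fold change of 10.82 (SE 0.77, edgeR adjusted p = 0.000619). By mean level it ranked 18 among the listed genes in mitochondria-associated RNA and 14506 in total RNA. The next gene by the naming rule was PGSC0003DMG400020177, at 31.9 ± 18.9 CPM in mitochondria-associated RNA and 3.69 ± 0.792 CPM in total RNA (SD, n = 3 each). Its log2 fold change was 3.11 (SE 0.47, edgeR adjusted p = 0.00472). At the other end, PGSC0003DMG400017447 had 0, 1 and 4 counts in mitochondria-associated RNA and 1329, 2567 and 1217 in total RNA, where it stood at 21.6 ± 6.36 CPM (SD, n = 3). Its log2 fold change was -8.15 (SE 0.64, edgeR adjusted p = 0.000854), a value that rests on 5 mitochondria-associated counts. PGSC0003DMG400020376 stood at 0.290 ± 0.176 CPM in mitochondria-associated RNA and 28.7 ± 10.99 CPM in total RNA (SD, n = 3 each), with a log2 fold change of -6.74 (SE 0.54, edgeR adjusted p = 0.00094). They were the extremes of 727 higher and 950 lower genes that met the rule. The files give no name, function or position for these IDs.

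**Figure D2:**
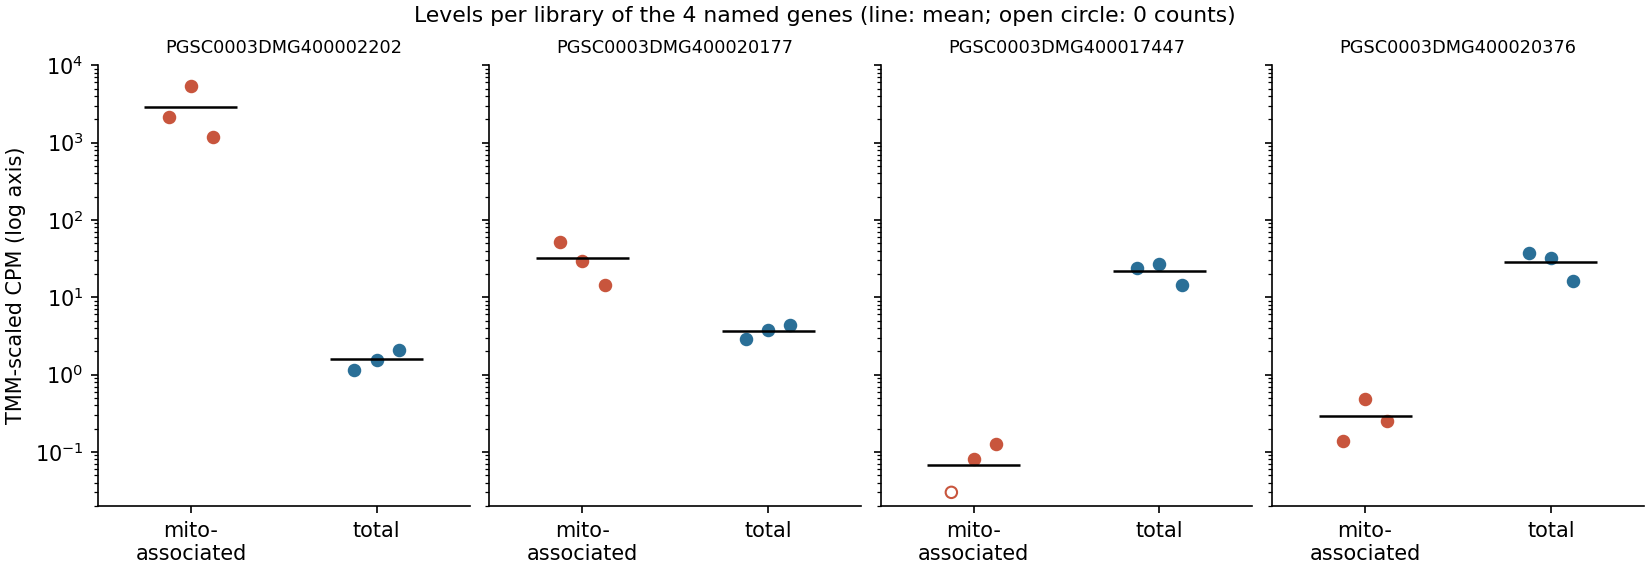
TMM-scaled CPM on a log axis for the 4 named genes, with 1 point per library, a line at each group's mean and an open circle for a library with 0 counts, drawn at the bottom of the axis. For PGSC0003DMG400002202 the lowest mitochondria-associated library (1178 CPM) is 574 times the highest total RNA library (2.05 CPM).

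A group of 104 genes (0.685%) was not detected in mitochondria-associated RNA, with 0 counts in all 3 libraries out of 70632302 pooled counts. In total RNA these genes had a median of 151 counts per library and mean levels of 0.812 to 9.59 CPM (median 2.03). A count of 0 allows up to 3 counts in the pooled libraries, or 0.045 CPM, so they were at least 17.9-fold to at least 212-fold lower (median of the bounds 44.9). All 104 passed edgeR's adjusted p of 0.05, but they were chosen by their 0 counts in the same libraries, so this is not a further test. A group with the opposite pattern cannot appear among the listed genes, since each has at least 50 counts in every total RNA library.

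Among the listed genes, lower calls were most frequent in the lowest decile of mean level. In the highest decile the order of higher and lower calls depended on the scaling and on single libraries. In the lowest decile of mean level (0.406 to 2.25 CPM, 1519 genes) 6 genes were higher and 433 lower in mitochondria-associated RNA. Without total RNA replicate 2 the lower calls of this decile were 257, without the other libraries in turn 296 to 458, and higher calls ranged from 0 to 15. In the highest decile (134 CPM and above, 1518 genes) 156 were higher and 58 lower, and with library size as the sole scaling 79 were higher and 85 lower. Scaling centred on the lower 5 deciles gave 14 higher and 420 lower genes in the lowest decile and 441 and 38 in the highest. The median log2 ratio to the mean of total RNA was -0.95, -0.94 and -0.99 in the lowest decile for mitochondria-associated replicates 1, 2 and 3, and 0.25, 0.27 and 0.38 in the highest. Across genes, the log2 fold change and the mean level had a Spearman correlation of 0.28, and of 0.16 within the upper 5 deciles (7590 genes), where genes are not independent replicates. The minimum of 50 counts in total RNA removes genes from the lowest levels in 1 direction. The mean level also includes the mitochondria-associated values, so a listed gene with a very low mean has to be lower there. Part of the excess of lower genes in the lowest decile, and of the correlation over all genes, is therefore fixed by the list. How large that part is was not tested. With 1 library left out, the highest decile held 131 higher and 59 lower genes without mitochondria-associated replicate 1, 17 and 20 without replicate 2, and 132 and 65 without replicate 3. It held 53 and 33 without total RNA replicate 1, 20 and 30 without replicate 2, and 109 and 40 without replicate 3. Limiting the test to a mean of at least 10 CPM gave 87 and 71. That limit removed no gene of the highest decile, but the scaling and the test were recomputed on the kept genes.

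**Figure D3:**
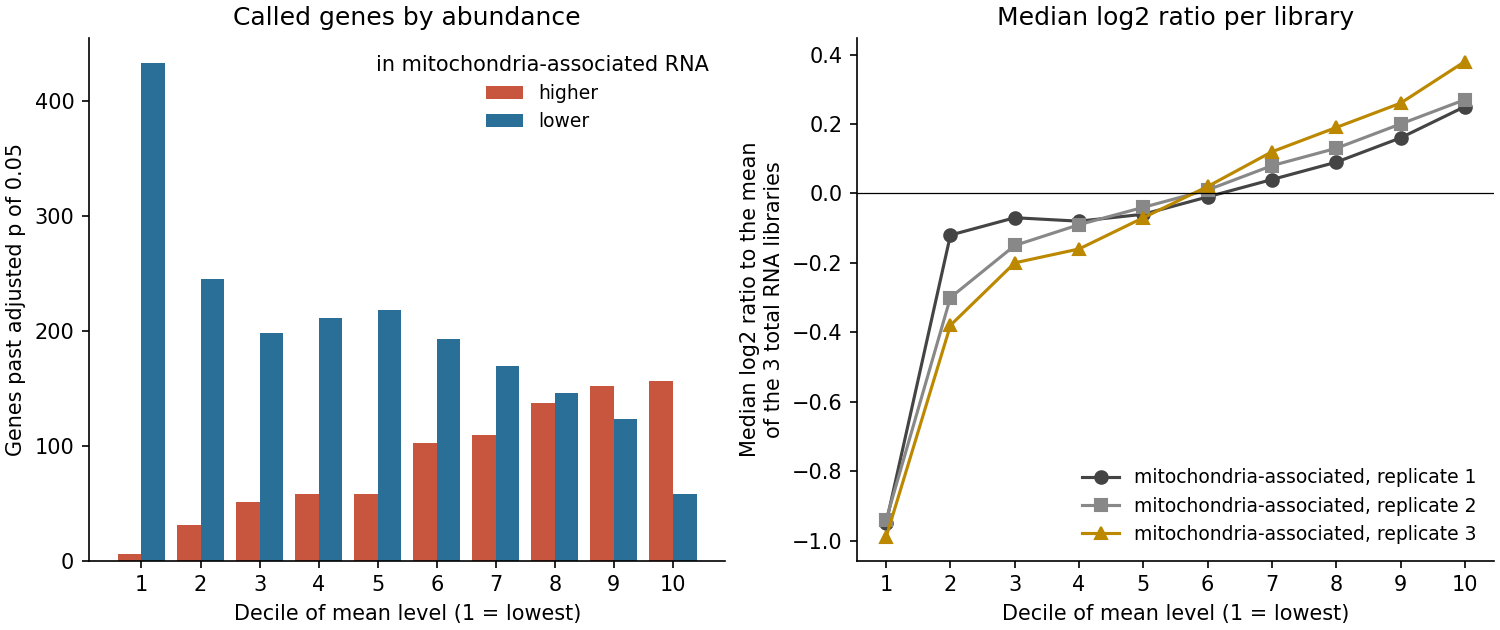
Left, genes past an adjusted p of 0.05 in each decile of mean level, as bars for genes higher and lower in mitochondria-associated RNA; right, the median log2 ratio of each mitochondria-associated library to the mean of the 3 total RNA libraries in each decile. From the lowest to the highest decile, lower calls go from 433 to 58 and higher calls from 6 to 156 (79 higher and 85 lower in the highest decile with library size as the sole scaling), and the medians of the 3 libraries go from between -0.99 and -0.94 to between 0.25 and 0.38.

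The authors' deposited table of the same comparison called more genes. At an adjusted p below 0.05 the authors' deposited table has 2495 genes higher and 3249 lower in mitochondria-associated RNA. All 860 genes called higher by edgeR, and 1992 of the 1994 called lower, were called in the same direction in the authors' deposited table. No gene had opposite calls. Fold changes had a Pearson correlation of 0.959 and a Spearman correlation of 0.996 across genes, and 98.2% had the same sign. The authors' deposited table gives log2 fold changes of 9.75 for PGSC0003DMG400002202, 2.73 for PGSC0003DMG400020177, -6.48 for PGSC0003DMG400017447 and -5.85 for PGSC0003DMG400020376, each closer to 0 than the edgeR value. The share of lower genes among the calls was 56.6% in the authors' deposited table and 69.9% with edgeR. Among calls past 2-fold this share was larger in both and differed less between them, with 677 higher and 2318 lower genes in the authors' deposited table and 473 and 1826 with edgeR.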

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

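All 4 named genes kept their direction and stayed past an adjusted p of 0.05 under each of the 18 alternatives that gave a value, with log2 fold changes of 10.04 to 11.2 for PGSC0003DMG400002202, 2.40 to 3.46 for PGSC0003DMG400020177, -9.39 to -7.50 for PGSC0003DMG400017447 and -7.15 to -6.20 for PGSC0003DMG400020376. Lower genes were 62.1% to 88.6% of the calls under 17 of the 18. The exception was TMM scaling centred on the lower 5 abundance deciles, chosen after seeing the data, which gave 2213 higher genes (1188 past 2-fold) and 42.5% lower; it moves all fold changes up by 0.23 on the log2 scale. Library size as the sole scaling gave 427 higher genes (250 past 2-fold), and DESeq2 gave 1587 higher genes. Of the 2854 calls, 2853 were also called in the same direction by DESeq2, 2825 with DESeq2 size factors, 2679 with upper quartile scaling, 2421 with library size alone, 2493 with the shifted TMM scaling, 2461 by limma-voom, 2582 with the replicate block and 1146 to 2300 with 1 library left out. Limiting the test to a mean of at least 10 CPM, an alternative chosen after seeing the data, gave 1450 genes, 396 higher and 1054 lower, and 183 and 890 past 2-fold, with 5795 fewer genes tested. The scaling was recomputed on the kept genes, and the log2 fold changes of all 4 named genes moved down. That of PGSC0003DMG400002202 went from 10.82 to 10.71 and that of PGSC0003DMG400020376 from -6.74 to -6.87. The smaller number of genes is therefore not the only change in this setting. Leaving out 1 library gave 1158 to 2716 genes, 133 to 845 higher and 1024 to 2007 lower, and past 2-fold 132 to 656 higher and 1023 to 1862 lower, with fewer samples in 1 group. Leaving out replicate 1 of both groups, also added later, gave 1004 higher and 2439 lower genes. The replicate block gave 3127 genes, 1014 higher and 2113 lower; not every library correlated best with its own number, since mitochondria-associated replicate 3 correlated at 0.39 with total RNA replicate 2 and at -0.05 with replicate 3. No low-count filter and a minimum of 50 counts in 3 samples removed 0 genes, so these settings tested nothing. Offsets for transcript length, alone or with the replicate block, and all alternatives for the gene lists, upstream AUGs and transcript features were not run, because the IDs could not be joined to names, lengths or sequences. Thinning total RNA to the mitochondria-associated depth gave 2809 genes. In the simulation 14 of 100 2-fold changes were called. It changed only 200 genes, which makes the adjusted threshold stricter than with the 2854 real calls, so this share does not carry over. Genes not called are not shown to be equal.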

Other observations

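Apart from the other splits of the samples and the planned scalings, the tests in this part were chosen after the results were seen. Some gene IDs share their last 6 digits and differ only in the digits before them (400 to 405), and their log2 fold changes were correlated. Across 706 pairs of neighbouring IDs with the same last 6 digits, log2 fold changes had a Spearman correlation of 0.50 and a Pearson correlation of 0.35. Pairs of consecutive numbers among the IDs that begin with 400 had a Spearman correlation of 0.06 (6310 pairs). The 2-sided permutation p was 1e-05 for the first, the smallest that 100000 resamples can give, and 2e-05 for the second, and both were 2e-05 after adjustment over the 2 relations. Pairs reshuffled within abundance deciles reached at most 0.25, against the observed 0.50, so similar abundance alone does not account for the relation. A candidate explanation is that paired IDs are parts of one transcript or overlapping models that share reads. For the 706 pairs this cannot be told apart from separate genes that behave alike, because their coordinates were not used here. Genes at 0 in all mitochondria-associated libraries were 22 of 916 IDs beginning with 402 (2.40%), 2 of 1000 beginning with 401 (0.20%) and 79 of 13144 beginning with 400 (0.60%), at median levels of 11.4, 11.5 and 17.4 CPM; these shares were not tested.

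Past 2-fold, lower genes outnumbered higher genes 3.86 times, and 2.61 times (without mitochondria-associated replicate 3) to 7.81 times (without mitochondria-associated replicate 2) with 1 library left out. Deeper sequencing of total RNA as the whole cause is argued against by a ratio of 3.71 after thinning to equal mean depth. The planned scalings gave 3.87, 5.08 and 8.75 (DESeq2 size factors, upper quartile, library size alone), but none of them moves fold changes up. Scaling centred on the lower 5 abundance deciles, which moves them up by 0.23 on the log2 scale, gave 1.25, but any shift upwards lowers this ratio, here through 1066 higher against 604 lower genes between 2-fold and 4-fold, so it decides nothing about the 2-fold surplus, for which the scaling stays open. Past 4-fold, where 935 of the surplus of 1353 lower genes lay, that scaling still left a ratio of 7.25 (885 against 122 genes), which argues against a shift of that size as the cause of the long lower tail. The authors' minimum of counts in total RNA leaves genes in place at a mean of at least 20 CPM and log2 changes up to 4. There the ratio was 1.66 between log2 changes of 1 and 4, which leaves the minimum open as a cause of the 2-fold surplus. It was 1.33 without mitochondria-associated replicate 3, 1.46 without total RNA replicate 3 and up to 3.32 without total RNA replicate 2. Between log2 changes of 2 and 4 the ratio was 4.35 (100 against 23 genes, 3.54 to 6.05 with 1 library left out). This argues against the minimum as the whole cause of the surplus of lower genes in that window. The 441 called genes more than 16-fold lower lie outside the window, so for them the minimum stays open. A true absence of some mRNAs from mitochondria, and the modified extraction of total RNA, which coincides with the groups, both stay open and were not tested.

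PGSC0003DMG400002202 lay far above the second-highest called gene, at a log2 fold change of 10.82 against 3.12. A single aberrant library is argued against, since the lowest mitochondria-associated level was 574 times the highest total RNA level. Reads shared with its listed neighbours in number are argued against for the 6 IDs examined only. These 3 next lower and 3 next higher listed IDs reached a log2 fold change of at most 0.56, and 0 of these 6 passed edgeR's adjusted p of 0.05. Neighbours that are not listed, and IDs with the same last 6 digits, were not examined, so reads shared with them stay open. That reads from the mitochondrial genome aligned to this gene stays open, because no sequence was compared. PGSC0003DMG400002202 was the 1 listed gene with a log2 fold change above 4. It had 65 counts in total RNA replicate 1, close to the authors' minimum of counts. Genes below that minimum are not listed, so the minimum stays open as a reason why it stood alone. An mRNA held almost wholly at mitochondria may give the same values, and that was not tested.

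Chance as the source of the 2854 calls (2299 past 2-fold) cannot be judged from the splits of the samples: 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. In the other 9 splits edgeR's quasi-likelihood test called 0 genes in each, with 12 to 775 genes at an unadjusted p below 0.05 against 5396 for the real split. Each of these 9 splits mixes both kinds of RNA in each group. The difference between the kinds then adds to the spread within groups and lowers the number of calls, so these values do not show what chance gives. No other tool was run on the splits. The authors' deposited fold changes differed from a refit with DESeq2's shrunken fold changes by a median of 0.018 without the replicate block and 0.011 with it, and the deposited table's 5744 calls exceeded those of both refits (4192 and 4698).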
